A study of Cicer arietinum with 8 samples.

How the data were processed

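Total RNA from 4 organs of chickpea (Cicer arietinum) was hybridised to a custom Agilent array in the 8x60k format, with 2 arrays per organ. Per the labels' protocols, shoots and roots came from 15-day-old seedlings raised in a culture room, and young pods and flower buds came from plants in the field. Per the labels' protocols, RNA was labelled in 1 colour (Cy3) from an oligo-dT primer carrying a T7 promoter, after addition of Agilent's 1-colour spike-in RNA mix. The array's design carried 61657 non-control probes of 60 bases for 39613 targets, of which 34379 had identifiers starting with TC and 5234 had identifiers starting with Ca_MJ. Of these targets, 19338 had 1 probe, 19446 had 2 and 829 had more.

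Scanner files were read for 7 of the 8 arrays; the scanner file of young pod replicate 1 was not analysed here. Per the file headers, the spot intensities were extracted with Agilent Feature Extraction 10.7.3.1, which subtracted background and removed spatial trends within each array. Per the file headers, the 7 arrays lay on 1 slide and were read in 1 scan, so neither slide nor scan separated them. The shoot and root arrays lay in slide row 1, and young pod replicate 2 and the bud arrays in slide row 2. On these 7 arrays row could not be told apart from the 2 growth settings. The row of young pod replicate 1 was not known. The deposited series table held an intensity for every probe on all 8 arrays. On each of the 7 arrays with a scanner file, its value equalled the processed signal for all 61657 probes, within a relative difference of 1e-05, so the table was linear, unscaled and uncentred for these arrays. For young pod replicate 1 the same scale was assumed from the shared table. Column medians of the table were 146 and 144 in shoot, 102 and 110 in root, 64.5 and 133 in young pod, and 118 and 137 in flower bud. The remaining columns used were the mean and background intensities deposited for each spot and the flags of 0 or 1 for spots well above background, saturated or outlying.

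Log2 processed signals were reduced by each array's 75th percentile over non-control probes. The 295 spots marked as outliers on the 7 arrays were left out of the scanner-based fit, and 1319 control spots were left out of every test. Probes were kept if they were well above background on every scanner array of at least 1 organ, which left 51357 probes of 36436 targets. Group means of all 4 organs were fitted together with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and a probe was called at a Benjamini-Hochberg adjusted p under 0.05, two-sided. Comparisons among shoot, root and flower bud used the 7 scanner arrays. Comparisons with the young pod and the counts of organ-preferred probes used the table of 8 arrays. The plan had assumed that this table would already be scaled, and the 75th percentile scaling was added when its values proved unscaled. Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6 read the files, and matplotlib 3.10.9 drew the plots.

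The design, the alternatives and the rule for naming targets were fixed before the data were examined. For probes without descriptions the rule took, in each comparison, the 2 targets with the largest positive and the 2 with the largest negative change. Their probes had to be called, be well above background and unsaturated on every scanner array of both organs, and have arrays that did not overlap between the organs. An organ-preferred probe was at least 2-fold higher in its organ than in each other organ, with all 3 differences called, and the 2 targets with the largest smallest difference were named per organ. Where a probe was not well above background on some array of the dimmer organ, the fold is given as a lower bound. For that bound, such an array took the higher of the probe's own signal and the lowest signal of any probe well above background on that array. Young pod replicate 1 had no flags, so its limit was assumed to be the highest such signal of the 7 other arrays, -4.38 on its own scale (log2), and folds are lower bounds where it lay below that. Such a bound is the smaller of the fold with that limit and the fold on the arrays with flags, a rule added after the data were seen.

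No gene names are reported. The description field of all 61657 probes was uninformative, and 0 of the 39613 target identifiers matched the gene table used here (assembly Cicar.CDCFrontier_v2.0). The 33 gene lists fixed beforehand relied on descriptions, so 0 of them were tested. Targets are therefore given by identifier and probe sequence. What the endings GE_h, GE_nh and ST in probe names stand for was not given in the sources used here. Some probes form pairs for the opposite strands of 1 site, with names ending in S and AS. The values named below for TC07236, TC17490, TC34389, TC24123 and TC04201 come from AS probes, and those for TC23621 from an S probe. The names of these AS probes also contain Xhyb, whose meaning was not settled here. For TC04201 the opposite strand is not reported. Size classes are those written in the probe names, for TC targets.

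The alternatives were normexp background correction with an offset of 50 on mean and background intensities, quantile normalization, the other source of values, no filter on dim probes, a filter for probes above background on all 7 arrays, the replicate number as a block, fits on the 2 organs compared, a variance trend, 1 probe per target, a size threshold, and leaving out each array in turn. No scaling between arrays and scaling to the spike-in RNA were added after the data were seen. The spike-in level of an array was the median log2 signal over 7 of the 10 spike-in probes, leaving out those near background or near the top of the range. The replicate numbers are shared between organs, but nothing in the labels ties equal numbers together.

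The fits were tested on simulated arrays that had each probe's real mean and residual spread, with 50 probes changed in 1 organ at each of 4 folds. For root against shoot, with 51357 probes, 0, 17, 29 and 37 of 50 probes changed 2-, 4-, 8- and 16-fold were called, together with 2 unchanged probes. For young pod against flower bud the corresponding numbers were 0, 13, 31 and 39 of 50, with 3 unchanged probes. For shoot-preferred probes they were 0, 10, 29 and 37 of 50, with 1 unchanged probe. For differences between strands in flower bud against root, with 4025 pairs, they were 0, 8, 32 and 41 of 50, with 2 unchanged pairs. Far fewer probes were changed in the simulation than differed in the data, where 42.1% were called in root against shoot. The Benjamini-Hochberg cutoff was therefore stricter in the simulation. These numbers give neither the power nor the number of false calls of the real fits. Precision was limited by the number of arrays, 2 per organ.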

Results

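The study profiled transcripts in 4 chickpea organs with an array designed from transcriptome sequences, and the comparisons below ask how the organs differ. Shoot, root, young pod and flower bud each had 2 arrays. Comparisons of young pod or flower bud with shoot or root set field-grown plants against 15-day-old seedlings. In these, organ cannot be told apart from growth setting, plant age or slide row. The same limit holds for the organ-preferred probes, which rest on such comparisons. Between 73.1% and 79.1% of the 61657 probes were well above background on each of the 7 arrays with scanner data, and 0 spots were saturated. The spike-in RNAs rose with their known amounts with slopes of 0.948 to 0.986 on the log scale, as the scanner software computed them. The 75th percentile of the signal was 928 and 881 in shoot, 647 and 714 in root, 416 and 927 in young pod, and 735 and 821 in flower bud. The labels do not say whether replicates came from separate plants, so every p-value measures only the spread between these arrays, which may be technical.

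Most transcripts were detected in all organs. Of the 51357 probes tested, 39896 (77.7%) were well above background on all 7 scanner arrays. Shoot had 47159 probes of 34267 targets above background on both arrays, root 43471 probes of 32090 targets, and flower bud 46232 probes of 33757 targets. Young pod, known from 1 array in this respect, had 47303 probes of 34302 targets. Detection restricted to 1 organ was rare, with 598 probes in flower bud, 485 in root, 378 in young pod and 366 in shoot.

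Root stood apart from the aerial organs. Across probes, root arrays correlated with shoot arrays at 0.791 to 0.807, with young pod arrays at 0.785 to 0.804 and with flower bud arrays at 0.719 to 0.745. Shoot and young pod correlated at 0.901 to 0.908, flower bud and young pod at 0.872 to 0.902 and flower bud and shoot at 0.863 to 0.890. Replicates of 1 organ correlated at 0.983 in shoot, 0.980 in root, 0.977 in flower bud and 0.957 in young pod, above every pair of different organs. Probes are not independent replicates, and these values describe the arrays. The first 3 principal components held 54.6%, 20.3% and 15.4% of the variance.

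**Figure D1:**
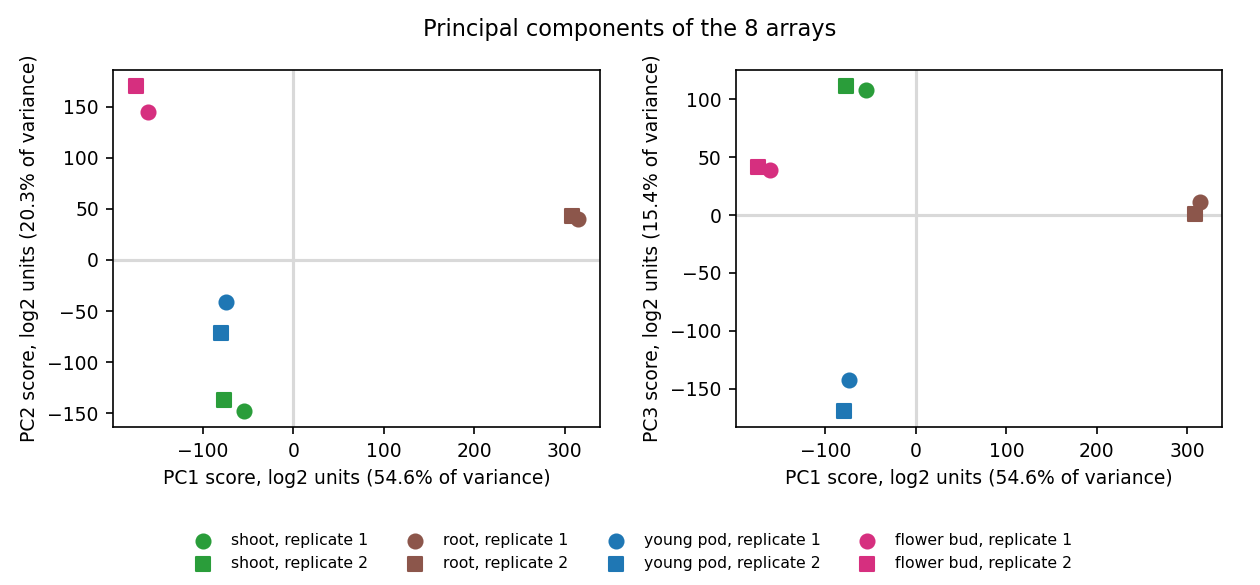
Scores of the 8 arrays on the first 3 principal components of the log2 signals of 51357 probes, with colour for the organ and shape for the replicate. Both root arrays lie at 308 and 314 on the first component, all other arrays lie between -175 and -55.0, and both arrays of each organ lie side by side.

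Young pod replicates differed more than the others. In young pod 10610 probes (20.7%) differed by over 2-fold between the replicates, against 4503 in flower bud, 4407 in root and 2728 in shoot. The shared estimate of the spread is therefore too small for the young pod and too large for the shoot.

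Roots and shoots of the seedlings differed at 21640 probes, 42.1% of the 51356 tested. Root was higher at 11362 probes of 9263 targets and lower at 10278 probes of 8365 targets, and at least 4-fold changes went more often down (5215 probes) than up (3559). TC07236 was 10900-fold lower in root (log2 change -13.42, SE 0.249, limma adjusted p = 4.37e-06), at -4.34 ± 0.23 in root and 9.07 ± 0.05 in shoot (log2 relative to the 75th percentile, SD, n = 2). Its probe read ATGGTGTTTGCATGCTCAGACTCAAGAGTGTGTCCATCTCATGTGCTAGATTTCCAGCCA, and the probe for the opposite strand of the same site was also lower, by a log2 change of -6.12. Ca_MJ0416629, probed by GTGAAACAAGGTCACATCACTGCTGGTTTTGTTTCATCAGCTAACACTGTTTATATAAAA, was 5480-fold lower in root (log2 change -12.42, SE 0.422, adjusted p = 7.55e-06). TC15506 was 2380-fold higher in root (log2 change 11.22, SE 0.404, adjusted p = 8.48e-06), from -4.37 ± 0.74 in shoot to 6.85 ± 0.36 in root. Its probe was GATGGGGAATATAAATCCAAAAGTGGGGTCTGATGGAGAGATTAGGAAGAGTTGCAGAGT, and its other probe rose by a log2 change of 12.46. TC03993 was 2390-fold higher in root (log2 change 11.22, SE 0.793, adjusted p = 8.79e-05), but the shoot arrays spread by an SD of 1.78, and the log2 change was 12.48 without shoot replicate 1 and 9.96 without shoot replicate 2. That of Ca_MJ0416629 was -13.03 and -11.81 without root replicates 1 and 2. With normexp background correction the changes of TC07236, Ca_MJ0416629, TC15506 and TC03993 were -11.92, -11.26, 9.82 and 10.14, and with spike-in scaling -14.11, -13.12, 10.52 and 10.52.

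Probes well above background on both arrays of 1 of these organs and on neither array of the other were mostly detected in shoot. Shoot had 3136 such probes, of which 2324 were called lower in root, and root had 846, of which 829 were called higher. Root arrays were dimmer, and their lowest signals well above background lay higher. These were -5.02 and -5.33 in root against -5.74 and -5.78 in shoot (log2 relative to the 75th percentile). A transcript at the same relative level could therefore fail detection in root alone. The same limit holds for detection in root against flower bud and young pod. Targets with Ca_MJ identifiers were higher in root at 17.8% of their 5003 probes and lower at 26.3%, while TC targets were higher at 22.6% of 46354 probes and lower at 19.3%. The share of called probes that were higher in root depended on the scaling. It was 52.5% with the 75th percentile, 62.8% with normexp background correction and 21.4% with spike-in scaling, and without scaling 6692 probes were higher in root and 14248 lower, so directions are relative to the bulk of the transcripts. Without shoot replicate 2 the count was 13998.

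Flower buds differed from shoots at 17516 probes, with 7550 higher in the bud and 9966 lower. TC11813 was 2690-fold higher in flower bud (log2 change 11.39, SE 0.276, adjusted p = 1.65e-05), at 7.40 ± 0.14 against -3.99 ± 0.42 in shoot (SD, n = 2), and its other probe rose by a log2 change of 11.42. The probe was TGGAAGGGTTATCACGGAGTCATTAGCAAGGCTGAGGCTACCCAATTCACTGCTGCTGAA. TC17490 was 2360-fold higher (log2 change 11.20, SE 0.692, adjusted p = 0.000178), and the opposite strand of its site rose by a log2 change of 7.61. TC16732 was 503-fold lower in flower bud (log2 change -8.97, SE 0.508, adjusted p = 0.000128), at -1.99 ± 1.02 against 6.98 ± 0.10 in shoot, and its other probe changed by -8.88. Without flower bud replicates 1 and 2 its log2 change was -9.69 and -8.25. TC23621 was 440-fold lower (log2 change -8.78, SE 0.374, adjusted p = 5.45e-05) on its probe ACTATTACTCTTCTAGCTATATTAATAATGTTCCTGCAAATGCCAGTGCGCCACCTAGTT. The opposite strand of that site had a log2 difference of -0.56 (adjusted p = 0.305), which did not pass the threshold. With normexp background correction the log2 changes of TC11813, TC17490 and TC23621 were 10.27, 9.71 and -7.39. With spike-in scaling they were 12.14, 11.95 and -8.04, and that of TC16732 was -8.23.

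Ca_MJ targets were lower in flower bud at 25.1% of their probes and higher at 10.9%, while TC targets were lower at 18.8% and higher at 15.1%. Flower buds alone detected 1173 probes of this pair and shoots alone 1573. Of the called probes 43.1% were higher in flower bud with the 75th percentile, 29.3% without scaling and 80.1% with spike-in scaling. The count fell to 8628 without shoot replicate 1, to 10075 without shoot replicate 2 and to 10971 without flower bud replicate 2.

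Flower buds and roots differed at 28524 probes, 55.5% of those tested. The bud was higher at 13483 probes and lower at 15041, with 6090 and 5936 of these at least 4-fold. TC07236, lower in root than in shoot, was also 2200-fold higher in flower bud than in root (log2 change 11.11, SE 0.249, adjusted p = 3.97e-06), and its opposite strand rose by a log2 change of 5.77. TC11813, higher in bud than in shoot, was 2140-fold higher in bud than in root (log2 change 11.07, SE 0.276, adjusted p = 3.97e-06). TC18514 was 2160-fold lower in flower bud (log2 change -11.08, SE 0.295, adjusted p = 4.05e-06), at -3.71 ± 0.23 against 7.37 ± 0.06 in root (SD, n = 2), with the probe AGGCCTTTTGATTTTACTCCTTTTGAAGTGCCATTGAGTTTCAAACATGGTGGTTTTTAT. TC28310 was 2090-fold lower (log2 change -11.03, SE 0.448, adjusted p = 9.79e-06). With normexp background correction the log2 changes of TC07236, TC11813, TC18514 and TC28310 were 9.48, 9.94, -10.00 and -9.10, and with spike-in scaling 12.55, 12.51, -9.64 and -9.59. Flower buds alone detected 3478 probes of this pair and roots alone 1590. With spike-in scaling 87.4% of the called probes were higher in flower bud, against 47.3% with the 75th percentile.

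**Figure D2:**
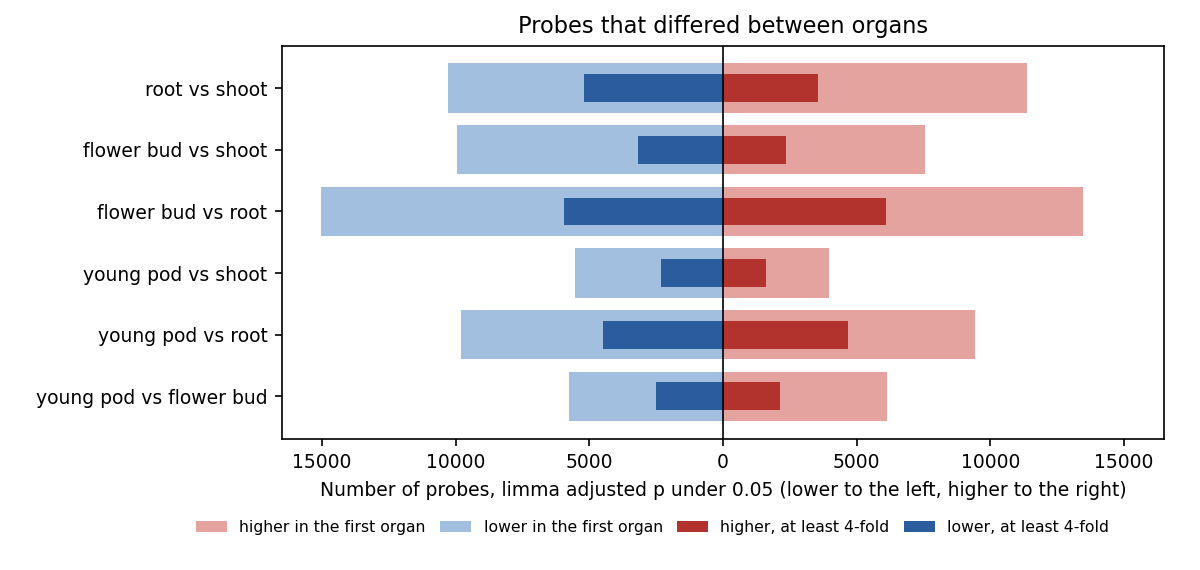
Number of probes with a limma adjusted p under 0.05 in each comparison of 2 organs, with probes lower in the first organ to the left and probes higher in it to the right. Pale bars count all called probes and dark bars those that changed at least 4-fold, and the longest bars belong to flower bud against root (13483 higher, 15041 lower).

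Young pods and shoots differed at 9522 probes, 18.5% of those tested. The pod was higher at 3982 probes and lower at 5540. TC07891 was 1390-fold higher in young pod (log2 change 10.44, SE 0.487, adjusted p = 2.68e-05), at 7.75 ± 0.89 against -2.70 ± 0.35 in shoot (SD, n = 2), and its other probe rose by a log2 change of 11.35. Without young pod replicates 1 and 2 its log2 change was 11.07 and 9.81. Its probe was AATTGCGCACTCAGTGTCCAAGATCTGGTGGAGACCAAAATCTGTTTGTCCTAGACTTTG. TC11251 was 1060-fold higher (log2 change 10.04, SE 0.498, adjusted p = 3.07e-05). TC16732, also lower in flower bud, was at least 3030-fold lower in young pod than in shoot (fitted log2 change -12.04, SE 0.575, adjusted p = 2.80e-05). This came from a different probe than the 503-fold change in flower bud, whose probe changed by -10.89 here. TC23621 was at least 691-fold lower (fitted log2 change -10.23, SE 0.381, adjusted p = 1.69e-05), while the opposite strand of its site had a log2 difference of 0.24 (adjusted p = 0.823). With spike-in scaling, on 1 young pod array, the changes of TC07891, TC11251, TC16732 and TC23621 were 13.02, 12.10, -9.62 and -8.13, so the 2 bounds do not hold with that scaling. Ca_MJ targets were lower in young pod at 16.2% of probes and higher at 5.28%, against 10.2% and 8.02% for TC targets. Of the called probes 41.8% were higher in young pod with the 75th percentile, 15.1% without scaling and 98.3% with spike-in scaling, which called 31832 probes. The count was 4079 without shoot replicate 1, 3795 without shoot replicate 2 and 6085 when the fit held these 2 organs alone.

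Young pods and roots differed at 19220 probes, with 9422 higher in the pod and 9798 lower. TC07236 was 2280-fold higher in young pod than in root (log2 change 11.15, SE 0.375, adjusted p = 2.13e-06), and its opposite strand rose by a log2 change of 5.80. TC18606 was 1190-fold higher (log2 change 10.21, SE 0.381, adjusted p = 2.89e-06), at 7.04 ± 0.46 against -3.17 ± 0.40 in root (SD, n = 2), with the probe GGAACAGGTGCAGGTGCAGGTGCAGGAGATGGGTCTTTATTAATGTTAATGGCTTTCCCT. TC34389 was 5140-fold lower in young pod (log2 change -12.33, SE 0.795, adjusted p = 1.83e-05), at -2.65 ± 1.16 in young pod and 9.68 ± 0.11 in root, and the opposite strand of its site changed by -4.70. Without young pod replicates 1 and 2 its log2 change was -13.15 and -11.51. TC01499 was at least 969-fold lower (fitted log2 change -11.28, SE 0.764, adjusted p = 2.30e-05), but its young pod arrays spread by an SD of 1.93, and the log2 change was -9.92 without young pod replicate 1 (adjusted p = 3.46e-05) and -12.65 without replicate 2. With spike-in scaling the changes of TC07236, TC18606, TC34389 and TC01499 were 14.31, 12.54, -10.50 and -7.27. Young pod detected 3472 probes that root did not, on its 1 array with flags, and root detected 1798 that this array did not. Spike-in scaling, on 1 young pod array, gave a median log2 difference over all probes of 2.50. On the same arrays the 75th percentile gave -0.143. Of the called probes 49.0% were higher in young pod with the 75th percentile. Without scaling 11936 probes were called.

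Young pods and flower buds, both taken from plants in the field, differed at 11905 probes, with 6127 higher in the pod and 5778 lower. TC07891 was 710-fold higher in young pod (log2 change 9.47, SE 0.487, adjusted p = 2.79e-05), and its other probe rose by a log2 change of 10.27. Without young pod replicates 1 and 2 its log2 change was 10.10 and 8.84. TC18606 was 520-fold higher (log2 change 9.02, SE 0.381, adjusted p = 1.57e-05). TC24123 was at least 1220-fold lower in young pod (fitted log2 change -11.61, SE 0.707, adjusted p = 5.20e-05), at -5.92 ± 1.67 against 5.69 ± 0.20 in flower bud (SD, n = 2), with the probe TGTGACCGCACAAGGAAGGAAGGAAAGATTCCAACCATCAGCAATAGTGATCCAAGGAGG. The opposite strand of its site fell less, by a log2 change of -1.66. TC18981 was at least 959-fold lower (fitted log2 change -11.41, SE 0.683, adjusted p = 4.72e-05). Without young pod replicate 1, where both signals were weaker than in replicate 2 and no background flags were held, the log2 changes of TC24123 and TC18981 were -10.43 and -10.32 (adjusted p = 0.000171 and 0.000208). Without replicate 2 they were -12.79 and -12.50. With spike-in scaling the changes of TC07891, TC18606, TC24123 and TC18981 were 11.31, 9.90, -9.22 and -9.12.

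Between pod and bud the median log2 difference was 0.19 for targets up to 1 kb and -0.23 for targets above 2 kb, a difference that was not tested. The replicate 1 arrays did not share the shift above 2 kb. Relative to each probe's mean over the 8 arrays, targets above 2 kb had medians of 0.09 and -0.31 on young pod replicates 1 and 2, and 0.02 and 0.20 on flower bud replicates 1 and 2. Spike-in scaling, on 1 young pod array, gave a median log2 difference over all probes of 1.23. On the same arrays the 75th percentile gave 0.027. Of the called probes 51.5% were higher in young pod with the 75th percentile and 26.6% without scaling, where 5826 probes were called. The count was 7245 without flower bud replicate 1, 5166 without flower bud replicate 2 and 7301 when the fit held these 2 organs alone.

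With the 75th percentile and all arrays, root had 4851 organ-preferred probes of 4002 targets (9.45% of the probes tested), flower bud 2093 of 1839, shoot 1843 of 1585 and young pod 1015 of 878. With spike-in scaling, on scanner arrays with 1 for young pod, young pod rather than root had the most preferred probes. The change of arrays is mixed with the scaling there. Among probes above background on all 7 arrays shoot had 1411 and flower bud 1254. At a 4-fold threshold the numbers were 2323 in root, 907 in flower bud, 510 in shoot and 393 in young pod. In shoot, TC16732 was at 7.20 ± 0.02 (SD, n = 2) and exceeded flower bud 472-fold, root 2540-fold and young pod 3030-fold (largest limma adjusted p of the 3 differences = 6.28e-05). These values of TC16732 come from the probe named for young pod against shoot, not from that named for flower bud against shoot. TC04201 was 164-fold higher in shoot than in flower bud, 224-fold higher than in young pod and at least 343-fold higher than in root, where 1 of 2 arrays was above background. Without flower bud replicate 2 the smallest log2 differences of TC16732 and TC04201 were 8.23 and 6.67, and without replicate 1 that of TC16732 was 9.53. The probe of TC04201 was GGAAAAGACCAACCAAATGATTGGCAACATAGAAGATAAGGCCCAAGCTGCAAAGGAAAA.

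The named root-preferred targets were not well above background on any scanner array of another organ. TC00905 was at 4.24 ± 0.27 in root (SD, n = 2), at least 963-fold higher than in flower bud and at least 1030-fold higher than in shoot and in young pod, with the probe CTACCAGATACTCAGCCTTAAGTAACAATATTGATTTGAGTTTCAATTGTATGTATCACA. TC18853 was at 4.56 ± 0.04 and at least 1200-fold higher than in each other organ, with the probe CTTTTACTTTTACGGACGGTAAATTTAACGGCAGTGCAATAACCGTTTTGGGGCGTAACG. In young pod, TC18637 was at 6.21 ± 0.10, at least 2050-fold higher than in flower bud, at least 2550-fold higher than in root and at least 3150-fold higher than in shoot, with the probe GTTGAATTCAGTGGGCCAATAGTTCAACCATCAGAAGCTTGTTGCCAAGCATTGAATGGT. TC16850 was at 6.43 ± 0.46 and at least 2870-fold higher than in each other organ. Both were above background on 1 of the 2 flower bud arrays and on 0 of the 2 root arrays. TC18637 was also above background on 1 of the 2 shoot arrays, and its bound for shoot averages that array with the other. The bounds of both targets for flower bud likewise average the detected array with the other. Without flower bud replicate 2 the smallest log2 differences of TC18637 and TC16850 fell from 12.23 and 12.16 to 10.17 and 10.14. Without flower bud replicate 1 they were 12.82 and 13.18, and without shoot replicate 2 that of TC18637 was 11.39. In flower bud, TC24123 was at 5.69 ± 0.20, at least 1870-fold higher than in root, at least 2680-fold higher than in shoot and 1380-fold higher than on the 1 young pod array with flags. TC18743 was at 4.15 ± 0.50 and at least 643-fold higher than in each other organ, with the probe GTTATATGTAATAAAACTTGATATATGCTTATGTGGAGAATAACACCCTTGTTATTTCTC. With spike-in scaling the smallest log2 differences of the named targets were 8.14 for TC16732, 5.86 for TC04201, 9.67 for TC00905, 9.63 for TC18853, 13.36 for TC18637, 13.69 for TC16850, 9.22 for TC24123 and 10.87 for TC18743. For TC16732, TC04201, TC00905, TC18853 and TC24123 these values lie below the smallest fold or bound given, which therefore does not hold with spike-in scaling. Folds in this paragraph and the preceding one came from the scanner arrays, with 1 array for young pod, and levels from both arrays of each organ.

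**Figure D3:**
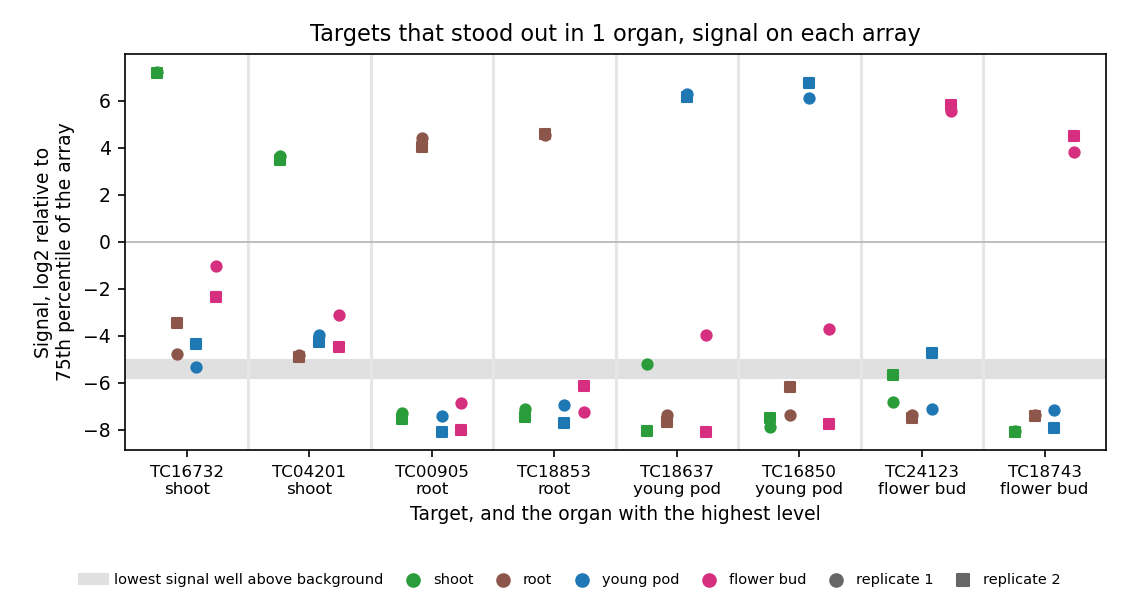
Signal of the 8 organ-preferred targets on each of the 8 arrays, as log2 relative to the array's 75th percentile, with colour for the organ and shape for the replicate. The grey band spans the lowest signals well above background on the 7 scanner arrays (-5.78 to -5.02), below which values have no order, as they have below the -4.38 assumed for young pod replicate 1, and the preferred organ lies between 3.46 and 7.22 on both of its arrays.

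The kinds of targets were spread unevenly over the organ-preferred sets. With 1 probe per target, 6.73% of 4860 Ca_MJ targets were shoot-preferred against 3.35% of 31519 TC targets (odds ratio 2.08, 95% interval 1.82 to 2.37, two-sided Fisher's exact test, adjusted p = 3.61e-25 over 8 tests). The order was the opposite in root (7.24% against 10.2%, adjusted p = 4.36e-11), young pod (73 of 4860 against 703 of 31519, adjusted p = 0.000872) and flower bud (2.55% against 4.38%, adjusted p = 5.01e-10). Targets above 2 kb were less often organ-preferred than targets up to 1 kb in root (7.17% against 11.6%, adjusted p = 1.16e-16), young pod (1.10% against 2.62%, adjusted p = 7.56e-10) and flower bud (2.36% against 5.13%, adjusted p = 2.54e-15). Targets above 2 kb also differed between arrays of 1 organ, with median deviations of 0.09 and -0.31 in young pod, 0.02 and 0.20 in flower bud and 0.03 and 0.06 in root. In shoot the shares were 2.69% and 3.09% (odds ratio 0.87, 95% interval 0.70 to 1.08, adjusted p = 0.192), which did not pass the threshold. The tests treat targets as independent, and they were chosen after the data were seen. Without shoot replicate 2 the counts were 639 in shoot and 607 in young pod, without flower bud replicate 2 they were 1106, 672 and 1093 in shoot, young pod and flower bud, and without young pod replicate 1 young pod had 1692. Without shoot replicate 1 they were 727 in shoot, 640 in young pod and 1231 in flower bud.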

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

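Control spots that the labels do not mention gave signal on the arrays, and the comparison with negative controls was chosen after this was seen. Of 420 spots with names starting with ERCC, 26.7% to 39.1% were well above background on the 7 scanner arrays. Of 156 spots with names starting with ETG, 20.5% to 33.3% were. Of 36 spots with names starting with DCP, 83.3% to 94.4% were. The negative control 3xSLv1 reached at most 0.97% of 308 spots. Spots named DarkCorner reached 11.4% (4 of 35) on shoot replicate 2 and at most 2.86% on the other arrays. Median DCP signals had the same order over the 7 arrays as those of the spike-in probes. They were 15715 against 26059 on root replicate 1, the highest, and 2323 against 4482 on young pod replicate 2, the lowest. DCP signal thus followed the added spike-in RNA, and no explanation was tested for the ERCC and ETG signals.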

How the results depend on the processing

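Of the alternative counts, 153 stayed within 1.5 times the count reported and 37 did not. The 153 include counts without an array of an organ outside the comparison, where only the shared spread could change. They also include counts among shoot, root and flower bud without young pod replicate 2, which could not change. All 558 alternative values of the named targets kept their direction and stayed called or organ-preferred. These targets were chosen for the largest changes in the same data, and several settings leave the estimated change itself unaltered. Their stability was therefore largely given in advance. Spike-in scaling moved some sizes below the bounds in the report, such as TC01499 to -7.27 and TC18853 to 9.63 on the log2 scale. Of the alternative shares of strand pairs changing in opposite directions, 71 were labelled the same as the share reported and 31 as moved. No scaling and spike-in scaling were chosen after the data were seen.

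Without scaling between arrays, 11936 probes were called in young pod against root and 5826 in young pod against flower bud, and 2478, 284 and 1212 were preferred in root, young pod and flower bud. With spike-in scaling, 31832 and 41521 were called in young pod against shoot and root, and 195, 935, 10885 and 1040 were preferred in shoot, root, young pod and flower bud. Spike-in scaling moved the median log2 difference of all probes to -0.56 in root against shoot, and to 0.68 and 1.35 in flower bud against shoot and root. In young pod against shoot, root and flower bud the medians were 1.86, 2.50 and 1.23. Some possible causes of the spike-in levels were tested under Other observations, and the cause was not settled. Scanner values with 1 young pod array gave 1688 young pod-preferred probes, and only probes above background on all 7 arrays gave 1254 flower bud-preferred probes, where fewer probes were tested. Fits on the 2 organs compared, with fewer arrays, gave 6085 for young pod against shoot, 7301 for young pod against flower bud and 658 young pod-preferred probes. At a 4-fold threshold 510, 2323, 393 and 907 probes were preferred in shoot, root, young pod and flower bud.

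Leaving out each array in turn gave 13998 to 21832 for root against shoot, 8628 to 17516 for flower bud against shoot, 23155 to 28524 for flower bud against root, 3795 to 11042 for young pod against shoot, 13623 to 20891 for young pod against root and 5166 to 14813 for young pod against flower bud. The preferred counts ranged from 639 to 1896 in shoot, 3439 to 4949 in root, 607 to 1692 in young pod and 1093 to 2340 in flower bud. A lone array was assumed to vary like the other organs. Leaving out young pod replicate 2 did not alter the counts among shoot, root and flower bud, since a lone array adds nothing to the scanner-based spread. The upper ends of 17516 and 28524 are therefore the reported counts themselves. With the replicate number as a block, 21376, 17213, 28513, 9221, 19119 and 11551 probes were called in these 6 comparisons; deviations of equal numbers correlated at -0.111 to 0.158 between organs, so the samples were taken to share only a number. The gene list alternatives were not run because no probe had a description. Probes near background limit the folds, and 7943 probes were above background on none of the 7 arrays.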

Other observations

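All tests in this part were chosen after the results were seen. Many sites gave signal from both strands. The array held 7155 pairs of probes whose sequences were exact reverse complements, named S and AS. Both strands were well above background in 42.7% of pairs in shoot, 38.9% in flower bud and 34.8% in root, and in 43.1% on the 1 young pod array. A single strand was above background in 34.4%, 37.6%, 36.0% and 44.3% of pairs in the same order. In 55 pairs the strand detected alone in 1 organ was the opposite of the strand detected alone in another organ.

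Where both strands of a site were called, they mostly changed in the same direction, but less often than probes of 1 target ending in GE_h. In flower bud against root, both strands were called in 1305 of 4025 pairs, and 252 of these (19.3%, 95% exact binomial interval 17.2 to 21.6) went in opposite directions. In the other 5 comparisons the share ran from 29 of 344 pairs (8.43%) to 80 of 616. Leaving out each array in turn gave 12.5% to 19.98% in flower bud against root, 4.72% to 9.85% in root against shoot, 7.10% to 14.1% in flower bud against shoot, 2.67% to 16.7% in young pod against shoot, 5.80% to 12.5% in young pod against root and 5.81% to 11.03% in young pod against flower bud. Directions depend on the scaling, and with spike-in scaling the share was 3.22% in flower bud against root. For targets with 2 probes ending in GE_h, 99 of 3815 pairs with both probes called went in opposite directions (2.60%), and for those ending in GE_nh 78 of 310 did (25.2%). The difference between strands, which a constant scaling of an array does not alter, changed at 1514 of the 4025 pairs in a limma fit of that difference. TC13349 rose on its S probe (log2 change 3.01, SE 0.228, limma adjusted p = 9.52e-05) and fell on its AS probe (-2.35, SE 0.228, adjusted p = 0.000267). TC23599 rose by 2.35 and changed by -2.33 on the opposite strand; these pairs were chosen after their values were seen, as the largest such changes.

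Targets with 2 probes ending in GE_nh resembled the strand pairs. In shoot 37.4% of 3509 such targets had a single probe above background, against 2.94% of 8591 targets ending in GE_h, and changes of the probes correlated at 0.405 against 0.883 in flower bud against root. Probes that shared 15 bases did so on opposite strands in 6 GE_nh targets and on the same strand in 0, against 1 and 6 for GE_h (two-sided Fisher's exact test, p = 0.00466).

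Labelling that copies both strands of 1 RNA could account for strands that change together, which stays open. Some pairs had strands that went in opposite directions wherever zero was set from the 75th percentile to the spike-in level, each strand by over 3 SE. In flower bud against root these were 19 of 501 pairs (3.79%, 95% interval 2.30 to 5.86), against 0.31% of GE_h pairs (0.12 to 0.63), and the intervals lay apart in root against shoot and flower bud against shoot too. Copying alone would not move strands apart, but the GE_h share does not give the error rate of strand pairs. On root replicate 1, 92.05% of GE_h probes were well above background, against 63.45% of S and 59.65% of AS probes. The comparison therefore does not decide whether labelling accounts for the pairs that went apart. The strand that GE_nh probes read is not known for most targets, so their share (4.81%) gives no error rate either. Antisense transcripts and RNA of other genes binding to 1 of the probes stay open for the pairs that went apart.

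The spike-in signal relative to the transcripts tended to go with the organ, though shoot and root overlapped. The spike-in level minus the 75th percentile was 5.01 and 4.50 in shoot, 5.89 and 5.01 in root, 3.76 and 4.25 in flower bud and 2.80 on the young pod array (log2). Labelling error that is independent between arrays is argued against only weakly. Of the 105 arrangements of the arrays into groups of these sizes, 3 had arrays as alike (exact permutation test, p = 0.0286, smallest possible 0.0095). The pattern had been seen in these same values before it was tested. The lone young pod array adds no spread to this test. The test cannot tell organ apart from slide row, growth setting or replicates labelled together. The 100 brightest probes could shift the rest by at most 0.078 of a range of 3.09. The rows of the slide did not overlap, with a gap of 0.25, and row cannot be told apart from seedlings against field-grown plants. A different share of messenger RNA in total RNA between organs is a possible explanation that was not tested.

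The young pod replicates differed by an SD of 0.91 on the log2 scale, against 0.56 to 0.63 in the other organs. Noise from a dim array is argued against as the whole cause, since the SD was 0.716 among the 12839 brightest probes, where the others reached at most 0.395. Adding a share of 1 other organ to either pod array left at least 0.625 there, at a fitted share of 39.5% flower bud in replicate 1, and removing the median of each length class left 0.685. A partial contribution of each may remain. The slide, scan and spike-in level of replicate 1 were not known here, so a technical difference between the 2 arrays stays open and was not tested. Pods of different stages or plants stay open as an untested biological difference.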
